A study of Mus musculus with 2 samples.

How the data were processed

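The deposited matrices gave raw counts, as UMIs per gene and per antibody tag in each droplet, for 2 captures of pooled CD45+ cells of the small intestine. The authors made these counts with Cell Ranger, whose software line in the file header reads Cell Ranger 4, after bcl2fastq 2.19.1. The genome build and annotation they used are not given in the sources used here. Each capture held cells of every mouse, marked by 15 hashtag antibodies, and the authors gave a table that assigns barcodes to mice. In capture 1, of 56242 barcodes listed, 16994 were multiplets and 532 negative, 24695 belonged to the 6 mice analysed and 14021 to other names. In capture 2 these numbers were 53959, 15748, 605, 23978 and 13628. The 9 other names of the table were not used here, since the labels give no group for them.

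Cells with fewer than 200 genes or more than 10% mitochondrial UMIs were left out (350 of 48673), as were 579 predicted doublets (Scrublet in scanpy 1.11.5, expected share 5%, 1.16% and 1.24% called in the captures). The 47744 cells left had a median of 4429 UMIs, 4382 in capture 1 and 4482 in capture 2. Counts were scaled per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with leidenalg 0.10.2 (resolution 1, seed 0) into 32 clusters. A cluster took the name of the cell type with most markers at least 2 times above all other cells and at 10 CPM or more, with a pseudocount of 5 CPM. A CD4 T or B cluster was named regulatory T or germinal centre B if that subset had at least 3 markers and more of the 10 leading genes. A cluster stayed unnamed with under 3 markers or with more leading genes of another type. It also stayed unnamed with a tie that leading genes did not break, or with as many leading genes of another type that had 3 markers. So did a cluster with over 3 times the median UMIs of the mice and at least 3 markers of a second type. Ties were broken by leading genes for monocytes (cluster 13) and gamma-delta T cells (cluster 20). Details of this rule were settled after the clusters were seen and before the diets were compared. Cluster 1 had B cell markers but was led by haemoglobin and Paneth cell genes, cluster 10 had B cell and ILC3 markers, and cluster 11 had as many CD8 T as CD4 T markers. Antibody names in the tag panel were taken as the feature table gives them.

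UMIs were summed per mouse and class over both captures, and classes with at least 20 cells in each of the 6 mice were tested (17, with 7 not tested). Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, as HFD minus chow. The adjusted p is that of Benjamini and Hochberg over the genes tested in a class, with a threshold of 0.05. CPM are the counts scaled by edgeR to a common library total, and the SE of a log2 change comes from the fit. Shares of cells were tested with edgeR on cell counts over 24 classes with total cells as offset and no composition factor, and with an exact two-sided permutation test. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), adjusted over 371 tests, and again with an estimated correlation. Lists of cell type markers (25) were adjusted apart, over 117 tests. Differences of the diet effect between a class and the other cells of the same mice were tested as an interaction with mouse as a block, for ILC3, cDC2, cDC1, macrophages and monocytes. Antibody tags were tested like genes.

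The cell type markers, the 23 gene lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The gene lists were fatty acid oxidation and PPAR targets, fatty acid synthesis, lipid uptake and storage, cholesterol synthesis, LXR targets, glycolysis, oxidative phosphorylation, oxidative stress response, unfolded protein response, heat shock and protein folding, immediate early and dissociation genes, NF-kappaB and inflammatory genes, type I interferon response, antigen presentation and interferon gamma response, type 2 programme, type 3 programme, cytotoxic programme, T cell checkpoint and activation, tissue homing and residence, cell cycle, macrophage tissue programme, secretory antibody programme and aryl hydrocarbon receptor targets. In ILC3, cDC2, cDC1, macrophages and monocytes, up to 10 genes higher and 10 lower with the largest log2 change were named, among genes with an adjusted p under 0.05, at least 20 CPM and no overlap between the mice of the diets. In other classes up to 3 per direction were named. Up to 4 members with the smallest p of each called list and a few genes fixed in advance were added. Segments and constant regions of immunoglobulins and T cell receptors, unnamed loci, Y-linked genes and Xist, haemoglobins and epithelial markers were not named by size. Genes of the text are a choice among these, a few of them are not reported here, and genes called in at least 5 classes were counted as shared.

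Gene positions came by gene ID from GENCODE M21 (GRCm38), where 32060 IDs (99.62%) matched. The tests were tried on simulated data with the depth of these libraries. The changed genes were drawn only among those at 20 CPM or more, so recovery of weaker genes was not tried. Of such genes changed 2-fold, 98.5% were recovered in ILC3, 100% in cDC2, 92.5% in cDC1, 95.5% in macrophages and 88.1% in monocytes and in CD8 T cells. At 1.5-fold it was 68.7%, 73.1%, 38.8%, 56.7%, 31.3% and 28.4%. Unchanged genes made up 7.2% to 9.2% of the calls, a share above the threshold of 0.05. A raised list was called in each of 6 classes, and 0 of 20 unchanged lists was. The simulated genes were drawn independently, so these draws cannot show how often lists of correlated genes are called in error. Another split of the 6 mice called 61 lists, against 96 for the diets. For shares, 84% of changed classes and 1.32% of unchanged classes were called in 100 draws. The changed classes were lowered by more than 2-fold, and each class varied between mice independently, by the same set spread. These draws therefore cannot show how often shares that vary together between mice are called in error. Another split of the 6 mice called 8 shares, against 5 for the diets. Alternatives were DESeq2 1.42.0 as test, its size factors or library totals as scaling, no filter on genes, each capture alone, equal cell numbers, doublets kept, at most 5% mitochondrial UMIs, at least 500 genes per cell, a clustering resolution of 2, TMM factors for shares, mouse number as a replicate block, and each mouse left out. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9, scikit-learn 1.9.0, data.table (1.17.8) and matplotlib 3.10.9.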

Results

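The series held single-cell RNA profiles of CD45+ cells, the white blood cells, sorted from the small intestine of C57BL/6 mice. It asked how gut immune cells differ after a short time on a 36% high-fat diet (HFD). There were 3 mice on a regular diet (chow) and 3 on HFD. Cells of all mice carried hashtag antibodies, were pooled and were loaded on 2 captures, so each capture held every mouse and its free RNA was common to both diets. After filtering, 47744 cells remained, with a median of 4429 unique molecular identifiers (UMIs) and 1864 genes per cell. Chow mice 1, 2 and 3 gave 6120, 6318 and 9126 cells with 40647480, 45131460 and 45761432 UMIs. HFD mice 1, 2 and 3 gave 10870, 7329 and 7981 cells with 59289940, 51446911 and 41104115 UMIs. Clusters were named from marker genes, so a name such as ILC3 or macrophage stands for cells that resemble that type. Of 24 classes, 17 had at least 20 cells in every mouse and were tested for genes. Libraries summed per mouse and class held 226871 to 17150071 UMIs.

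In order to find which cell types took a different share of the sorted cells, cell counts per class were compared between diets. CD8 T cells, which kill infected cells, made up 7.99% ± 4.40 of cells in chow mice and 1.08% ± 0.330 in HFD mice (mean ± SD, n = 3 each). CD4 T cells, which direct other immune cells, made up 5.48% ± 2.72 in chow mice and 1.05% ± 0.0531 in HFD mice. Neutrophils fell from 0.853% ± 0.334 to 0.115% ± 0.0963. The small cluster 23, with as many markers of neutrophils as of eosinophils and a median of only 710 UMIs per cell, fell from 1.77% ± 1.19 to 0.0814% ± 0.0557. The 55 cells of the unnamed cluster 27 went from 0.271% ± 0.344 to 0.0118% ± 0.00231. Log2 ratios were -2.88 ± 0.74 (SE) for CD8 T cells, -2.38 ± 0.69 for CD4 T cells, -2.90 ± 0.83 for neutrophils, -4.42 ± 0.95 for cluster 23 and -4.36 ± 1.17 for cluster 27. The edgeR adjusted p was 0.0128 for cluster 23 and 0.0225 for the other 4, and no class of the 24 was called higher. The exact two-sided permutation p was 0.1 for each of the 5, the smallest that 3 against 3 mice can give. It was 0.1 too for NK and ILC1 cells and regulatory T cells, which edgeR did not call. Adjusted over the 24 classes, the permutation p was 0.343 for each of these classes. CD4 T cells lost the call without chow mouse 1 (adjusted p = 0.143), chow mouse 2 (0.0898), HFD mouse 1 (0.133), HFD mouse 2 (0.0689) or HFD mouse 3 (0.116). CD8 T cells lost it without chow mouse 1 (0.0772), HFD mouse 1 (0.112) or HFD mouse 3 (0.116), and neutrophils without the same mice (0.0827, 0.133 and 0.116). Cluster 23 lost it without HFD mouse 1 (0.0699) or HFD mouse 3 (0.116), and cluster 27 also without chow mouse 2 (0.233) or HFD mouse 2 (0.0689). With TMM factors, a scaling that assumes most classes keep their share, the adjusted p was 0.0627 for CD4 T cells, 0.0514 for CD8 T cells and cluster 23, 0.0627 for neutrophils and 0.0863 for cluster 27. B cells were not called with all 6 mice: they made up 9.09%, 4.94% and 41.7% of the cells of chow mice 1, 2 and 3, and 40.3%, 15.7% and 40.5% in HFD mice (log2 0.79, adjusted p = 0.67). Without chow mouse 3 they were called higher (log2 2.20, adjusted p = 0.0405), and NK and ILC1 cells were called lower (-1.45, adjusted p = 0.0405). Among cells outside the B-like classes (B, germinal centre B and clusters 1 and 10), a setting chosen after seeing the data, log2 ratios were -1.74 for CD4 T cells (adjusted p = 0.00693) and -2.29 for CD8 T cells (adjusted p = 0.00132), and plasma cells were called higher (1.42, adjusted p = 0.0106). With plasma cells left out as well, also chosen after, the log2 ratios were -1.55 (adjusted p = 0.0117) and -2.09 (adjusted p = 0.00273).

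**Figure D1:**
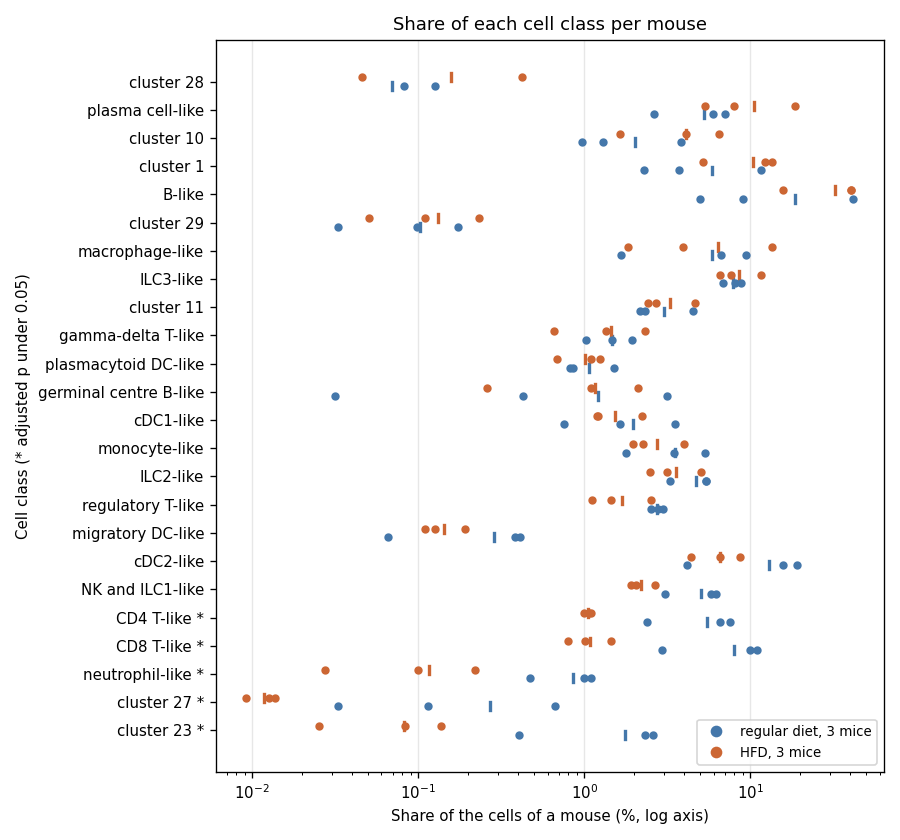
Share of each class in percent of the sorted cells of a mouse, on a log axis, with a point per mouse, and a star marking an adjusted p under 0.05. CD8 T cells averaged 7.99% in chow mice and 1.08% in HFD mice.

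In order to see which cell types differed between the diets in their RNA, UMIs were summed per mouse and class and tested with edgeR. Type 2 conventional dendritic cells (cDC2), which present antigen to CD4 T cells, had 1133 genes higher and 965 lower in HFD mice. Type 1 conventional dendritic cells (cDC1), which present antigen to CD8 T cells, had 247 higher and 354 lower, and macrophages had 198 higher and 291 lower. Group 3 innate lymphoid cells (ILC3), a source of interleukin 22 in the gut, had 169 higher and 128 lower. Monocytes had 153 higher and 109 lower, and group 2 innate lymphoid cells (ILC2) had 144 higher and 49 lower. Regulatory T cells had 0 by edgeR, with 628 genes at an unadjusted p under 0.05, and 20 by DESeq2. The 17 classes together gave 4326 calls, 2319 of them higher in HFD mice. The total was 1880 without chow mouse 1, 1773 without chow mouse 2, 2249 without HFD mouse 1 and 2326 without HFD mouse 2. It was higher without chow mouse 3 (5865) or HFD mouse 3 (4544). Of 312 calls of named genes, 149 were kept whichever mouse was left out. The mice of the 2 diets did not overlap for 11.4% (cluster 11) to 35% (cDC2) of genes over the 17 classes, where chance gives 10%.

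**Figure D2:**
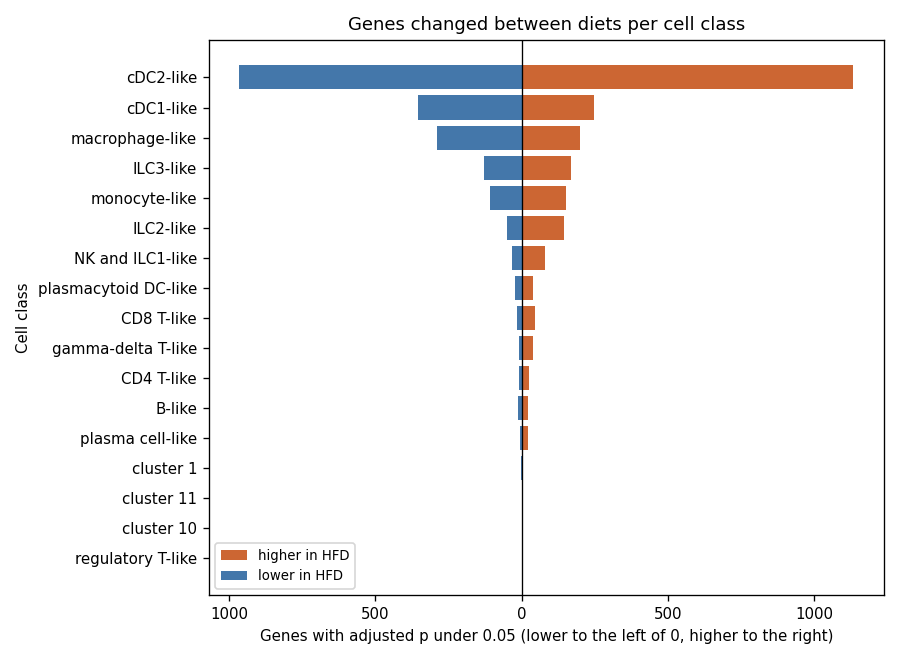
Number of genes with an adjusted p under 0.05 in each of the 17 classes, with those higher in HFD mice to the right and those lower to the left. The cDC2 class had 1133 and 965.

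In order to see how ILC3 differed between the diets, 10555 genes were tested in this class. Ifng, which encodes interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, GRCm38), rose from 28.6 ± 10.4 to 82.9 ± 4.99 normalised counts (CPM, mean ± SD, n = 3 mice each), a log2 change of 1.505 ± 0.18 (SE; edgeR adjusted p = 0.00432). Slc15a2, a peptide transporter (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962), rose by 1.29 ± 0.20 (adjusted p = 0.00756). Cd83 rose from 192 to 373 CPM (adjusted p = 0.00733), and Il7r, the receptor that binds interleukin 7, by 0.54 on the log2 scale (adjusted p = 0.00582). Antxr2, an anthrax toxin receptor, fell from 1187 ± 258 to 621 ± 99.8 CPM (log2 -0.94 ± 0.14, adjusted p = 0.00743). Sema6a fell from 220 to 116 CPM and Diaph3 from 40.2 to 19.2 CPM. Il22, which encodes the epithelial defence cytokine interleukin 22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047), was at 1031 ± 167 CPM in chow mice and 848 ± 107 CPM in HFD mice. Its log2 change of -0.28 ± 0.11 did not pass (adjusted p = 0.201). The same held for Il17a (-0.54, adjusted p = 0.387), Il17f (0.37, 0.455), Csf2 (-0.11, 0.756) and Ahr, the aryl hydrocarbon receptor (0.42, 0.0666). The class had 169 genes higher and 128 lower, or 146 and 198 with library totals alone as scaling. The count was 46 without chow mouse 1, 32 without chow mouse 2, 758 without chow mouse 3, 104 without HFD mouse 1 and 159 without HFD mouse 2. Of 37 named genes, 12 kept their call without any single mouse, among them Ifng, Slc15a2, Cd83, Il7r, Antxr2, Sema6a and Diaph3.

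The ILC3 class joined clusters 6 and 16, which were compared as settings chosen after seeing the data; Il22 was among the genes that set clusters apart. In cluster 6, Il22 went from 857 ± 142.8 to 591 ± 27.5 CPM (log2 -0.54 ± 0.10, adjusted p = 0.00374) and Ahr from 90.4 to 130 CPM (adjusted p = 0.0139). In cluster 16, Il22 was at 1578 ± 294 and 1582 ± 154 CPM. The difference of the Il22 change between both clusters was -0.53 ± 0.11 (adjusted p = 0.0296; 37 of 9584 genes called). Vegfa, a growth factor for blood vessels, went from 291 to 580 CPM in cluster 16 (adjusted p = 0.0138), and its difference between clusters was -1.15 (adjusted p = 0.0635).

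**Figure D3:**
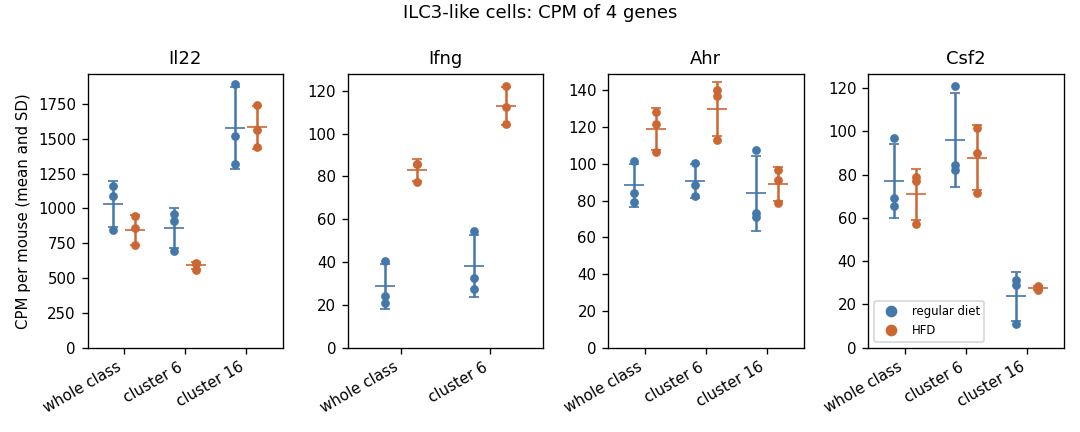
CPM of Il22, Ifng, Ahr and Csf2 per mouse in the whole ILC3 class and in its clusters 6 and 16 (Ifng without cluster 16). Ifng rose from 28.6 to 82.9 CPM in the whole class, and Il22 went from 857 to 591 CPM in cluster 6.

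In order to see which gene groups moved together in ILC3, lists of genes were tested with camera. Immediate early and dissociation genes, which react within minutes to a stimulus or to tissue digestion, had 15 members higher and 0 lower of 24, with a mean log2 change of 0.50 (adjusted p = 1.4e-13). Among them were Egr1 (log2 0.90), Btg2 (0.53) and Zfp36 (1.23). Cell cycle genes had 4 of 17 lower, with Top2a from 37.2 to 12.8 CPM and Rrm1 at -0.73 (mean -0.70, adjusted p = 4.56e-07). The cytotoxic programme had 3 of 16 higher (mean 0.44, adjusted p = 5.29e-06), with Ifng, Klrk1 (0.55) and Xcl1 (0.69). Beside them, NK and ILC1 markers rose in ILC3 (mean 0.48, adjusted p = 0.00368, and 0.735 with an estimated correlation). Homing genes had 3 of 21 higher (adjusted p = 7.19e-05) and T cell checkpoint and activation genes 4 of 14 (adjusted p = 0.000525). The NF-kappaB list had 4 higher, among them Birc3 (0.70) and Tnfaip3 (0.55), and 1 lower of 21 (adjusted p = 0.00695), and oxidative phosphorylation was lower with 0 of 51 members called (adjusted p = 0.0115). The counts adjusted over the list alone were 17 higher and 1 lower for immediate early genes, 10 lower for the cell cycle and 3 higher for the cytotoxic programme. All of these calls were lost with an estimated correlation: adjusted p = 0.58 for the first 5 lists, adjusted p = 0.71 for NF-kappaB and adjusted p = 0.652 for oxidative phosphorylation. The NF-kappaB call ended without HFD mouse 3 (0.19), and the oxidative phosphorylation call without chow mouse 2 or HFD mouse 2 (0.0532). Of the genes named, Zfp36 lost its call without chow mouse 2 (0.0548), Top2a without HFD mouse 1 or HFD mouse 2 (0.0712), Rrm1 without chow mouse 1 (0.0781) or HFD mouse 1, Klrk1 without chow mouse 1 or chow mouse 2 (0.0707), and Xcl1 without chow mouse 1 (0.0932), chow mouse 2, HFD mouse 2 or HFD mouse 3.

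In order to learn how cDC2 differed between the diets, 12159 genes were tested. The chemokine genes Ccl3 and Ccl4, which attract other white blood cells, rose from 28.3 to 110 CPM and from 130 to 508 CPM, and Ccl9 rose from 8.70 ± 3.58 to 35.8 ± 7.87 CPM (log2 2.15 ± 0.26, n = 3 mice each, edgeR adjusted p = 0.00125). Ccr2, the receptor by which monocytes leave the bone marrow, rose from 31.2 ± 8.42 to 102 ± 9.70 CPM (adjusted p = 0.00072). Tnf, the inflammatory cytokine, rose from 19.9 to 57.5 CPM (adjusted p = 0.00044). Ly75, which encodes the uptake receptor DEC-205, fell from 272.4 ± 62.3 to 93.4 ± 27.1 CPM (log2 -1.55 ± 0.21, adjusted p = 0.00195). Mical2 fell from 160 to 56.9 CPM, Scin from 114 to 35.7 CPM and Zbtb7c from 36.7 to 7.65 CPM. Immediate early genes had 19 members higher and 3 lower of 25 (mean 0.73, adjusted p = 2.8e-08), with Jun from 252 to 1002 CPM and Egr1 from 213 to 774 CPM. Heat shock genes had 7 of 15 higher (mean 0.79, adjusted p = 0.000211), with Hspa1a from 197 to 601 CPM, and the NF-kappaB list had 12 higher and 2 lower of 23 (adjusted p = 0.00614). Homing genes had 8 higher and 2 lower of 21 (adjusted p = 0.00624), with Itgb7, an integrin of gut homing, from 100 to 148 CPM. Oxidative phosphorylation had 10 of 51 lower (mean -0.14, adjusted p = 5.29e-06), with Ndufa4 at -0.44 and Ndufb2 at -0.40 (adjusted p of Ndufb2 0.0514 without chow mouse 1). Adjusted over the list alone, 21, 7, 12 and 12 members were higher and, for oxidative phosphorylation, 14 lower. The adjusted p with an estimated correlation was 0.58 for immediate early genes and for oxidative phosphorylation, 0.711 for heat shock, 0.652 for NF-kappaB and 0.64 for homing.

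Further lists were higher in cDC2 and lost their call when a mouse was left out. The type I interferon response had 7 of 26 higher (adjusted p = 0.00523; 0.0549 without HFD mouse 3), with Slfn5 at 1.19. The antigen presentation list had 9 higher and 1 lower of 30 (adjusted p = 0.0432; 0.181 without chow mouse 3, lost also without HFD mouse 2 or HFD mouse 3), with Irf1 at 0.61 and H2-D1 at 0.44. The type 3 programme had 4 of 14 higher (adjusted p = 0.0388; 0.098 without HFD mouse 2, lost also without chow mouse 1 or chow mouse 2), with Batf and Rora. The cytotoxic programme had 3 of 9 higher (camera adjusted p = 0.0141), and lost its call without HFD mouse 3 (0.103) or HFD mouse 1. Its called members were the chemokine genes Ccl3 and Ccl4 and Klrd1 at 0.94. Klrd1 lost its own edgeR call without chow mouse 1 (0.0745) or chow mouse 2. The macrophage tissue programme had 6 higher and 1 lower of 19 (adjusted p = 0.0199; 0.122 without HFD mouse 2, lost also without chow mouse 3), with Mrc1 at 1.36 and Axl at 1.64. Monocyte markers (2 higher and 1 lower of 6, mean 0.90, adjusted p = 0.137) and macrophage markers (3 higher and 1 lower of 9, mean 0.40, adjusted p = 0.34) did not pass in cDC2. Nor did ILC3 markers (3 higher and 1 lower of 8, mean 0.59, camera adjusted p = 0.286). The same held for CD4 T markers (mean -0.42, 0.34) and CD8 T markers (mean -0.17, 0.654). Cell cycle genes had 3 higher and 1 lower of 32 (adjusted p = 0.00943; 0.347 without HFD mouse 2, lost also without chow mouse 1 or chow mouse 3), and Ccnb2 (0.56 in the class, its call lost whichever mouse was left out, with 0.131 without HFD mouse 1) was at -0.23 in cluster 17. Adjusted p values of the 6 called lists with an estimated correlation were 0.71, 0.715, 0.627, 0.58, 0.627 and 0.835 in this order. The class joined clusters 3 and 17, and of its 2098 calls 99% and 96.3% of those compared had the same direction inside them, with 595 and 371 kept. The clusters hold the same cells that gave the calls, so this agreement was largely set in advance. The median log2 size of these calls was 0.601 in the class and 0.443 in cluster 3. For those compared in cluster 17 it was 0.587 and 0.481. The 2098 became 1024 without chow mouse 1, 1015 without chow mouse 2, 1222 without HFD mouse 1 and 1286 without HFD mouse 2.

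In order to see how cDC1 differed between the diets, 8814 genes were tested, with 247 higher and 354 lower. Slc15a2 rose from 15.8 ± 4.57 to 117 ± 38.1 CPM (log2 2.73 ± 0.26, n = 3 mice each, edgeR adjusted p = 0.000452). S100a10 rose from 15.9 to 58.5 CPM and Ccr2 from 40.6 to 97.1 CPM, and Ddit3, a transcription factor of the stress response, from 35.2 to 89.0 CPM (adjusted p = 0.00119). Sema6d, a semaphorin, fell from 49.1 ± 16.4 to 6.16 ± 3.67 CPM (log2 -2.92 ± 0.33, adjusted p = 0.000816). Col25a1 fell from 78.8 to 13.9 CPM, Mitf from 54.0 to 18.1 CPM and Tnfaip2 from 213 to 71.5 CPM. Immediate early genes had 14 higher and 1 lower of 24 (mean 0.72, adjusted p = 3.6e-12), with Jun from 243 to 1092 CPM. Heat shock genes had 4 of 15 higher (mean 0.70, adjusted p = 3.29e-06), with Hspa1a from 193 to 689 CPM. Homing genes had 8 higher and 1 lower of 19 (adjusted p = 0.00134), and the cytotoxic list had 2 of 5 higher (adjusted p = 0.0199). These were Ccl3, from 3.33 to 22.4 CPM, and Ccl4. The edgeR call of Ccl4 was lost without HFD mouse 2 (0.201), HFD mouse 1, chow mouse 1 or chow mouse 2. Cell cycle genes were higher (mean 0.70, adjusted p = 3.96e-07) with Hells, a chromatin remodeller, called (log2 0.99) of 30 members. The secretory antibody programme had 4 of 13 higher (adjusted p = 0.00194), with the antibody joining chain Jchain from 185 to 562 CPM, which belongs to plasma cells. Adjusted over the list alone, 19, 9, 9, 3, 5 and 5 members were higher in these 6 lists. With an estimated correlation the adjusted p was 0.58, 0.669, 0.58, 0.58, 0.655 and 0.58 in the same order. The unfolded protein response had 2 of 22 higher (adjusted p = 0.046, and 0.791 with an estimated correlation; 0.302 without chow mouse 2, lost also without chow mouse 3 or HFD mouse 1). The count of 601 genes became 251 without chow mouse 2, 317 without HFD mouse 1 and 352 without HFD mouse 2, and Jchain lost its call without chow mouse 2 (0.0511). The changes of Jchain and the antibody genes Igkc and Igha were not called different from those in the other cells (0.22, 0.56 and 0.03). Whether RNA of plasma cells reached cDC1 before the cells were pooled was not tested.

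In order to compare macrophages between the diets, 10197 genes were tested, with 198 higher and 291 lower. Gdf15, a stress cytokine (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), rose from 26.4 ± 13.2 to 143.1 ± 47.6 CPM (log2 2.67 ± 0.28, n = 3 mice each, edgeR adjusted p = 0.000325). Gpnmb, a membrane glycoprotein, rose from 7.44 ± 0.145 to 40.6 ± 17.1 CPM, and Trem2, a receptor for lipids, from 16 ± 4.87 to 44.9 ± 10.4 CPM (adjusted p = 0.00264). Cd36, a receptor for fatty acids, rose from 420 ± 97.0 to 824 ± 122 CPM (adjusted p = 0.00428). Ccl24, a chemokine that attracts eosinophils (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049), fell from 55.7 ± 17.3 to 4.15 ± 0.696 CPM (log2 -3.63 ± 0.29, adjusted p = 9.01e-05). Gpr55 fell from 115 ± 36.5 to 20.6 ± 7.73 CPM, Vdr, the vitamin D receptor, from 33.4 to 8.48 CPM, and Il1b, the inflammatory cytokine, from 1295 ± 218 to 606 ± 148 CPM (adjusted p = 0.00268). C1qa was at 2707 and 2441 CPM (adjusted p = 0.541). Immediate early genes had 12 higher and 3 lower of 25 (adjusted p = 0.000124), with Rhob at 1.19 and Nr4a2 at -1.32. The aryl hydrocarbon receptor targets had 2 of 5 lower (adjusted p = 0.000465), with Asb2 (-0.67) and Tiparp (-0.55), and cell cycle genes were higher (mean 0.58, adjusted p = 0.000124) with 1 of 20 called. Adjusted over the list alone, 14, 0 and 2 members were higher in these lists and 5, 3 and 0 lower. The adjusted p with an estimated correlation was 0.58, 0.58 and 0.627. Asb2 lost its call without HFD mouse 2 (0.0766) and Tiparp without chow mouse 1 (0.15), chow mouse 2, HFD mouse 1 or HFD mouse 2.

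In macrophages 4 further lists were called and lost their call when a mouse was left out, while the lipid uptake list was not called (adjusted p = 0.493). The fatty acid oxidation list had 4 higher and 1 lower of 21 (adjusted p = 0.033; 0.106 without HFD mouse 1, lost also without chow mouse 3), and Plin2, which coats lipid droplets, went from 510 to 847 CPM (adjusted p = 0.0098; 0.0796 without chow mouse 2, lost also without chow mouse 1 or HFD mouse 2). Cholesterol synthesis had 2 of 21 lower, Pmvk (-0.96) and Cyp51 (-0.94) (adjusted p = 0.0139; 0.103 without HFD mouse 2, lost also without chow mouse 1 or HFD mouse 1). Pmvk lost its call without chow mouse 1, chow mouse 2 or HFD mouse 2 (0.0706), and Cyp51 without chow mouse 1 or HFD mouse 2 (0.0901). Oxidative phosphorylation was lower with 0 of 50 members called (adjusted p = 0.0199; 0.567 without HFD mouse 2, lost also without chow mouse 1 or HFD mouse 1). Heat shock genes were higher with 0 of 15 called (adjusted p = 0.0113; 0.352 without HFD mouse 1, lost also without chow mouse 2 or chow mouse 3). With an estimated correlation the adjusted p was 0.58, 0.72, 0.867 and 0.791 in this order. The class count of 489 became 131 without chow mouse 1, 177 without chow mouse 2, 245 without HFD mouse 1, 141 without HFD mouse 2 and 803 without HFD mouse 3.

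In order to compare monocytes between the diets, 8757 genes were tested, with 153 higher and 109 lower. Exoc3l2 rose from 6.83 ± 1.87 to 39.6 ± 7.46 CPM (log2 2.48 ± 0.27, n = 3 mice each, edgeR adjusted p = 0.00606). Gdf15 rose from 13.02 to 74.7 CPM (adjusted p = 0.0118; 0.0773 without chow mouse 1, lost also without chow mouse 2) and Gpnmb from 9.12 to 48.6 CPM (adjusted p = 0.0107; 0.0748 without chow mouse 1). Ccl24 fell from 49.0 to 11.2 CPM (adjusted p = 0.0184; 0.102 without chow mouse 1, lost also without HFD mouse 1 or HFD mouse 2). Mt2, a metallothionein, fell from 54.1 to 19.8 CPM (adjusted p = 0.00754; 0.0734 without chow mouse 1). Immediate early genes had 15 of 25 higher (mean 0.64, adjusted p = 2.91e-08), heat shock genes 3 of 14 (mean 0.74, adjusted p = 5.29e-06) and oxidative phosphorylation 3 of 51 lower (adjusted p = 8.42e-05). The type I interferon response was higher with 0 of 28 members called (mean 0.44, adjusted p = 9.75e-06), and cholesterol synthesis with 0 of 17 (adjusted p = 0.0141; 0.121 without chow mouse 3). Adjusted over the list alone, 17, 8, 0, 4 and 2 members were higher in these 5 lists. The adjusted p with an estimated correlation was 0.58, 0.673, 0.589, 0.627 and 0.58. The count of 262 became 5 without chow mouse 1, 17 without chow mouse 2, 47 without HFD mouse 1, 31 without HFD mouse 2 and 534 without HFD mouse 3. Of 29 named calls only that of Exoc3l2 was kept without any single mouse.

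**Figure D4:**
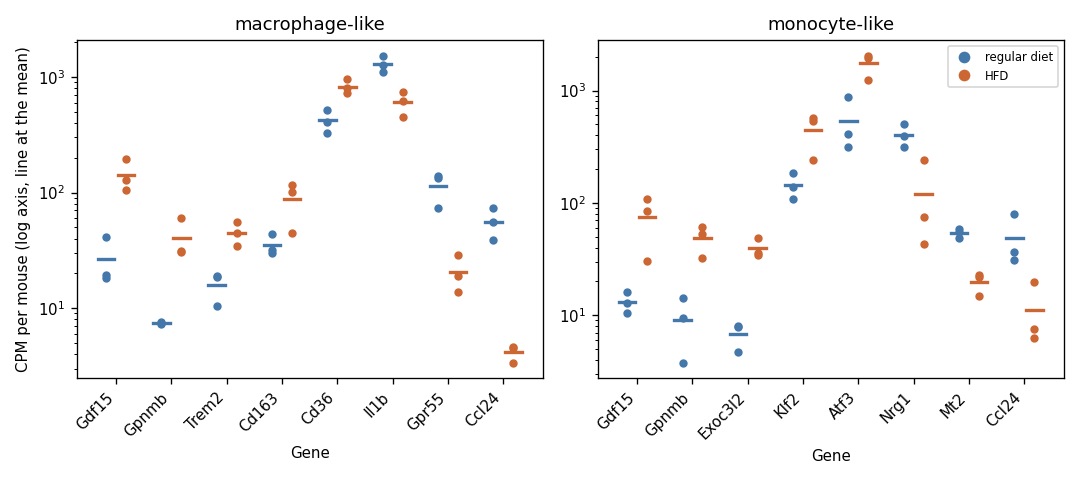
CPM per mouse on a log axis, with a line at each mean, for 8 genes in macrophages and 8 in monocytes. Macrophage Gdf15 rose from 26.4 to 143.1 CPM and Ccl24 fell from 55.7 to 4.15 CPM.

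In order to find genes that moved in many cell types, calls were compared across the 17 classes. Slc15a2 rose in 14 classes, with log2 changes from 0.77 to 2.73 across all 17. In B cells it rose from 126 to 406 CPM (log2 1.67 ± 0.15, n = 3 mice each, edgeR adjusted p = 9.35e-06), and in NK and ILC1 cells from 105 to 363 CPM. Its call ended in plasma cells without chow mouse 2 (0.18), chow mouse 1, chow mouse 3, HFD mouse 1 or HFD mouse 3, and in plasmacytoid dendritic cells without HFD mouse 1 (0.154), chow mouse 1, chow mouse 2 or HFD mouse 3. Dusp1 and Rhob rose in 10 classes, Klf6 in 9, and Jun, Atf3, Klf2 and Adgre5 in 8. Gm47283, a locus on chromosome Y, rose in 10 of the 13 classes in which it was tested (log2 1.08 to 2.37 over the 13). Cwc25, a splicing factor, fell in 9 classes, Antxr2 in 8, and Nfil3 and Chp1 in 6. Egr1 rose in 7 classes and fell in CD4 T and CD8 T cells. In all, 47 genes were called in at least 5 classes, 34 of them higher and 13 lower.

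In order to compare the other lymphoid cells between the diets, their genes were tested in the same way. In ILC2, Slc15a2 rose from 69.9 to 206 CPM, Sema3e from 15.03 to 52.3 CPM and Plin2 from 36.4 to 93.4 CPM (log2 1.35 ± 0.20, n = 3 mice each, edgeR adjusted p = 0.00243), while Top2a fell from 61.5 to 15.9 CPM. Il13, a type 2 cytokine, went from 66.0 ± 10.0 to 36.7 ± 15.6 CPM (adjusted p = 0.0354; 0.22 without HFD mouse 2, lost also without chow mouse 1, chow mouse 2 or HFD mouse 1), and Il5 (-0.69, adjusted p = 0.0996) and Areg (-0.04, 0.934) did not pass. Immediate early genes (13 of 23), NF-kappaB genes (5 of 21) and homing genes (5 of 16) were higher in ILC2 and cell cycle genes (2 of 16) lower, with adjusted p of 1.45e-16, 5.29e-06, 4.44e-06 and 1.16e-07. Adjusted over the list alone, 18, 6 and 8 members were higher and, for the cell cycle, 4 lower. In NK and ILC1 cells, which also carried the T cell gene Cd3e at 289.8 CPM, Klrk1 for the activating receptor NKG2D rose (log2 0.71, adjusted p = 0.00446), and Samd4 fell from 62.5 to 15.4 CPM. Gzmb, a protease of killer cells, went from 214 to 365 CPM (adjusted p = 0.0337; 0.203 without chow mouse 1, lost also without chow mouse 2, HFD mouse 1 or HFD mouse 2), and Ifng from 110 to 198 CPM did not pass (adjusted p = 0.102). The cytotoxic programme had 5 of 19 higher, 12 adjusted over the list alone (adjusted p = 9.6e-10), while CD8 T markers (mean -0.56, adjusted p = 1.13e-06) and CD4 T markers (-0.35, adjusted p = 0.0256) fell in this class. Its NK and ILC1 markers rose (0.40, adjusted p = 0.000587), and so did ILC3 markers (0.37, 3 of 5 higher, adjusted p = 0.0217). With an estimated correlation the adjusted p was 0.58 for each of the 5 gene lists, 0.541 for the CD8 T markers and 0.735 for the other 3 marker lists. The ILC2 count of 193 became 85 without chow mouse 1, 73 without chow mouse 2, 340 without chow mouse 3, 92 without HFD mouse 1 and 64 without HFD mouse 2, and it split into 123 higher and 98 lower with library totals. The NK and ILC1 count, 78 higher and 32 lower, became 23 without chow mouse 1, 50 without chow mouse 2, 51 without HFD mouse 1, 32 without HFD mouse 2 and 176 without HFD mouse 3, and with library totals it was 63 and 42.

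T cells also differed between the diets. In CD8 T cells, Xcl1, a chemokine, rose from 203 to 392 CPM (log2 0.98 ± 0.13, n = 3 mice each, edgeR adjusted p = 0.001), Eomes, a transcription factor of killer and memory cells, from 48.1 to 177 CPM, and Frmd5 from 5.71 to 70.7 CPM, while Pak1 fell from 117 to 35.3 CPM. The cytotoxic programme had 2 of 19 higher in CD8 T cells (adjusted p = 0.000723; 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). NK and ILC1 markers (mean 0.83, adjusted p = 0.00368) and gamma-delta T markers (0.37, adjusted p = 0.0402) rose in the same class (0.735 for both with an estimated correlation), and Ifng (0.58, adjusted p = 0.338), Gzma (0.33, 0.356) and Gzmb (-0.33, 0.538) did not pass. In CD4 T cells, Pard3 rose from 10.9 to 78.1 CPM, Egr1 fell from 1134 to 269 CPM and Cwc25 from 264 to 117 CPM. Homing genes had 3 of 22 higher and T cell checkpoint and activation genes 2 of 16, 9 and 6 adjusted over the list alone (adjusted p = 0.000525 and 1.17e-05; adjusted p = 0.58 for both with an estimated correlation), and S1pr1, the receptor for exit from tissue, rose by 1.40 (0.0549 without HFD mouse 3, lost also without HFD mouse 1). In gamma-delta T cells, Pak1 fell from 668 to 324 CPM, and checkpoint genes rose (2 of 11, 4 adjusted over the list alone, adjusted p = 2.45e-06; adjusted p = 0.58 with an estimated correlation). In regulatory T cells, Il10 was at 938 and 428 CPM (log2 -1.20 ± 0.43, adjusted p = 0.38) and Foxp3, which defines these cells, at -0.67 (0.581); the antigen presentation list was lower (mean -0.31, adjusted p = 0.000134; adjusted p = 0.655 with an estimated correlation). CD8 T cells had 44 genes higher and 17 lower, and the count was 32 without chow mouse 1, 13 without chow mouse 2 and 32 without HFD mouse 1. CD4 T cells had 25 and 8, or 19 and 11 with library totals, and the count was 8 without chow mouse 2, 17 without HFD mouse 1 and 21 without HFD mouse 2. Gamma-delta T cells had 40 and 8, and the count was 15 without chow mouse 1, 73 without HFD mouse 1 and 10 without HFD mouse 2. Regulatory T cells had 0 by edgeR (628 at an unadjusted p under 0.05, 20 by DESeq2), but 92 without chow mouse 3, 3 without HFD mouse 1, 73 without HFD mouse 2 and 1 without HFD mouse 3.

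B cells, plasma cells, plasmacytoid dendritic cells and the unnamed clusters were compared in the same way. B cells had Slc15a2 as their clearest change, and Nfil3 went from 26.8 to 13.5 CPM (adjusted p = 0.0235; 0.138 without chow mouse 1, lost also without chow mouse 3 or HFD mouse 1). Their type I interferon response fell (1 of 25 members called, 7 adjusted over the list alone, mean -0.45, camera adjusted p = 1.89e-05; adjusted p = 0.627 with an estimated correlation). In plasma cells, which secrete antibody, Fos went from 1013 to 2128 CPM (adjusted p = 0.019; 0.0795 without HFD mouse 3, lost also without HFD mouse 1 or HFD mouse 2), and Jchain (0.31, adjusted p = 0.245) and Igha (0.31, 0.309) did not pass. Cell cycle genes fell in plasma cells with 0 of 28 members called, 19 adjusted over the list alone (mean -0.93, adjusted p = 6.12e-10; adjusted p = 0.654 with an estimated correlation). The class joined clusters 2, 30 and 31, and only the 51 cells of cluster 30 had cycling markers (8, against 0 in the other 2). In cluster 2 alone, a setting chosen after seeing the data, the list was not called (mean -0.17, 16 members tested, adjusted p = 0.178). In plasmacytoid dendritic cells, a source of type I interferon, Atp10a fell from 120 to 47.6 CPM and Desi1 from 70.8 to 26.2 CPM, and cholesterol synthesis genes rose (2 of 20, 5 adjusted over the list alone, mean 0.42, adjusted p = 5.29e-06; adjusted p = 0.589 with an estimated correlation). Slc15a2 rose in clusters 1, 10 and 11 by 1.76, 1.70 and 1.51. B cells had 20 genes higher and 13 lower, or 13 and 17 with library totals, and the count was 6 without chow mouse 1, 15 without chow mouse 3, 17 without HFD mouse 1 and 12 without HFD mouse 3. Plasma cells had 20 and 7, or 25 and 192 with library totals, and the count was 46 without chow mouse 1, 10 without chow mouse 2, 0 without HFD mouse 1, 7 without HFD mouse 2 and 5 without HFD mouse 3. Plasmacytoid dendritic cells had 39 and 24, and the count was 20 without chow mouse 1, 31 without chow mouse 2, 191 without chow mouse 3 and 20 without HFD mouse 1. Clusters 1, 10 and 11 had 6, 1 and 4 genes. Cluster 1 had 3 without chow mouse 1, 12 without chow mouse 2, 13 without chow mouse 3 and 2 without HFD mouse 2; cluster 10 had 2 without chow mouse 2 and 4 without chow mouse 3; cluster 11 had 11 without chow mouse 3, 1 without HFD mouse 1 and 7 without HFD mouse 3.

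In order to see which gene groups moved across cell types, 23 lists were compared over the 17 classes. Immediate early and dissociation genes were higher in 10 classes and lower in 1, regulatory T cells (0.157 without HFD mouse 3). Homing genes were higher in 9 classes and lower in 0, T cell checkpoint genes and the cytotoxic programme were higher in 6 and lower in 0, and oxidative phosphorylation was higher in 0 and lower in 8. The classes with a higher cytotoxic programme included cDC1 and cDC2. The members called there were Ccl3 and Ccl4, which the NF-kappaB list also holds, and in cDC2 also Klrd1. Heat shock genes were higher in 6 and lower in 3, NF-kappaB genes 5 and 1, cholesterol synthesis 5 and 3, cell cycle genes 3 and 3, the type 3 programme 3 and 1, and the type I interferon response 2 and 4. Antigen presentation was higher in 1 and lower in 3, and the unfolded protein response in 2 and 1. LXR targets and the secretory antibody programme were higher in 2 and lower in 0. Fatty acid oxidation, lipid uptake, the macrophage tissue programme and the type 2 programme were higher in 1, and glycolysis and aryl hydrocarbon receptor targets lower in 1. Fatty acid synthesis and the oxidative stress response were called in 0. Of 371 tests, 96 passed, 66 higher and 30 lower, and 46 of them did so without any single mouse. With an estimated correlation 0 passed, with a smallest adjusted p of 0.58.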

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

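The tests of this part were chosen before their results were seen. In macrophages, 20 of 16630 genes had a diet effect that differed from that in the other cells of the same mice, 12 more positive and 8 more negative. The make-up of the other cells changed with the diet, with CD8 T cells falling from 7.99% to 1.08% of all cells, so such a difference can also come from the mix of cells. Among them were Cd36 (difference of log2 changes 1.31, edgeR adjusted p = 0.0253), Lonrf3 (1.74, 0.0357), Samd4 (2.96, 0.0253) and Gpr55 (-1.61, 0.0497). The rise of Samd4 in macrophages lost its own call without chow mouse 2, chow mouse 3 or HFD mouse 2 (log2 1.03, adjusted p = 0.259). In cDC1, 2 genes differed, Sema6d (-2.75, adjusted p = 0.00529) and S100a10 (2.07, 0.00529). In monocytes, 2 genes differed, Ms4a4a (-1.94, adjusted p = 0.0397) and Il22ra2, which the naming rule did not give and which was chosen after its values were seen. In ILC3 and in cDC2 the edgeR count was 0, with 1141 and 1910 genes at an unadjusted p under 0.05 and no other tool run. The difference for Ifng in ILC3 was 2.47 ± 0.36 (adjusted p = 0.197) and did not pass. It was larger than the rise in ILC3 itself (log2 1.505), so by this fit Ifng fell in the pooled other cells, where the CD4 T and CD8 T shares fell too.

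The antibody tags, which no comparison of the report used, differed between the diets in 10 of 17 classes, with 128 tags tested in each. There were 13 tags in cDC2 (4 higher, 9 lower), 8 in monocytes (1 and 7), 7 in plasma cells (1 and 6), 5 in CD4 T cells (1 and 4), 5 in plasmacytoid dendritic cells (1 and 4) and 4 in ILC2 (1 and 3). CD8 T and gamma-delta T cells had 2 each, and clusters 1 and 11 had 1 each, all lower. Most tags called were thus lower in HFD mice. Whether tag counts fell in common was not tested, and tags were not tested with a mouse left out. The other 7 classes had 0 by edgeR, with 9 to 22 tags at an unadjusted p under 0.05 and no other tool run.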

How the results depend on the processing

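Settings chosen after seeing the data were the ILC3 clusters 6 and 16 alone, the cDC2 clusters 3 and 17 alone, the plasma cell cluster 2 alone and the shares outside the B-like classes, with or without plasma cells. The cause of each change below was not tested, except that leaving out mice, cells or a capture leaves fewer data. Of the 4326 calls, 4276 were shared with DESeq2 size factors, 4141 with library totals, 3367 with the DESeq2 test, 4185 with no filter on low counts, 2236 with capture 1, 2120 with capture 2, 2180 with equal cells per mouse, 3805 with doublets kept, 4245 with a mitochondrial share under 5% and 3789 with the finer clustering. Among named genes, 329 kept direction and side of the threshold with size factors, 278 with the DESeq2 test (51 weaker), 233 with equal cells (90 weaker), 209 with capture 1 (103 weaker) and 232 with capture 2 (89 weaker). In 0 of 17 classes did all 3 pairs of mice of the same number correlate over 0.1 (-0.11 to 0.154 overall), so the numbers were not taken as pairs. In cDC1 all 3 were positive (0.066, 0.089 and 0.069), each chow mouse was closest to the HFD mouse of its number, and in cDC2 2 of 3 were; the block gave 725 and 2114 calls there. The fit with mouse number as a replicate block is given only here, and in it the share of B cells was called higher (1.27, adjusted p = 0.0482). Of simulated 1.5-fold changes, all in genes at 20 CPM or more, 31.3% were recovered in monocytes, 28.4% in CD8 T cells and 38.8% in cDC1.

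With the DESeq2 test the calls were 62 in CD4 T, 1 in cluster 1, 2 in cluster 11, 205 in plasma cells, 29 in plasmacytoid dendritic cells and 20 in regulatory T cells. At clustering resolution 2.0 they were 16 in B cells and 3 in plasma cells. With library totals only they were 217 in plasma cells and 3 in regulatory T cells. With no filter they were 199 in B cells, 181 in CD4 T, 209 in CD8 T, 433 in ILC2, 850 in ILC3, 312 in NK and ILC1, 1064 in cDC1, 39 in cluster 1, 18 in cluster 10, 41 in cluster 11, 167 in gamma-delta T, 850 in macrophages, 695 in monocytes, 595 in plasma cells, 191 in plasmacytoid dendritic cells and 213 in regulatory T cells. With equal cells per mouse they were 18 in CD4 T, 12 in CD8 T, 127 in ILC2, 60 in NK and ILC1, 319 in cDC1, 1269 in cDC2, 3 in cluster 1, 2 in cluster 11, 28 in gamma-delta T, 55 in macrophages, 141 in monocytes, 4 in plasma cells and 18 in plasmacytoid dendritic cells. With mouse number as replicate block they were 105 in B cells, 171 in ILC3, 2 in cluster 1, 1 in cluster 11, 103 in gamma-delta T, 0 in monocytes, 1 in plasmacytoid dendritic cells and 44 in regulatory T cells. In capture 1 only they were 14 in B cells, 15 in CD4 T, 5 in CD8 T, 78 in ILC2, 187 in ILC3, 7 in NK and ILC1, 385 in cDC1, 2 in cluster 1, 2 in cluster 11, 10 in gamma-delta T, 228 in macrophages, 106 in monocytes and 8 in plasmacytoid dendritic cells, with 58 lists. In capture 2 only they were 8 in B cells, 3 in CD4 T, 112 in ILC2, 69 in NK and ILC1, 125 in cDC1, 1299 in cDC2, 1 in cluster 11, 4 in gamma-delta T, 135 in monocytes and 3 in plasma cells. Cluster 6 only gave 641 calls, cluster 16 only 26, cluster 3 only 626 and cluster 17 only 441. With an estimated correlation 0 lists were called, with a smallest adjusted p of 0.58.

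When each mouse was left out in turn, calls ranged from 6 to 35 in B cells, 8 to 33 in CD4 T, 13 to 77 in CD8 T, 64 to 340 in ILC2, 32 to 758 in ILC3, 23 to 176 in NK and ILC1, 251 to 787 in cDC1, 1015 to 2403 in cDC2, 2 to 13 in cluster 1, 1 to 4 in cluster 10, 1 to 11 in cluster 11, 10 to 73 in gamma-delta T, 131 to 803 in macrophages, 5 to 534 in monocytes, 0 to 46 in plasma cells, 20 to 191 in plasmacytoid dendritic cells and 0 to 92 in regulatory T cells. Lists called ranged from 79 to 96 and shares called from 0 to 7. Log2 ratios of shares ranged from -2.74 to -2.08 for CD4 T, -3.28 to -2.58 for CD8 T, -4.96 to -4 for cluster 23, -4.9 to -2.47 for cluster 27 and -3.74 to -2.41 for neutrophils. With TMM factors for shares these ratios were -1.9, -2.48, -4.08, -4.03 and -2.58, and 0 classes were called by edgeR at the threshold.

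Over the mice left out, log2 ratios of shares that turned direction reached 0.28 for ILC3, -0.74 for cDC1, 0.54 for cluster 11, 1.02 for cluster 29, -0.57 for gamma-delta T, -0.82 for germinal centre B, 0.62 for macrophages, -0.73 for monocytes and -0.25 for plasmacytoid dendritic cells at their other end. Gzma in NK and ILC1 reached 0.74, and the list heat shock and protein folding in B cells an adjusted p of 1.54e-07.

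Directions turned for the values below, of which Vegfa in ILC3, Hells, Ccnb2 and Mcm2 in cDC2 and the heat shock list in B cells had been called. In capture 1 only, Gzma in CD8 T was at -0.1, Areg in ILC2 at 0.05, Csf2 in ILC3 at 0.06 and the share of gamma-delta T at 0.03, and in capture 2 only the share of plasmacytoid dendritic cells was at 0.06. Without chow mouse 1, Areg was at 0 and the shares of cluster 11, monocytes and plasmacytoid dendritic cells at -0.04, 0.06 and 0.27. Without chow mouse 2, the shares of cDC1, cluster 11 and gamma-delta T were at 0.37, -0.07 and 0.21. Without chow mouse 3, Areg was at 0.12, Csf2 at 0.09, and the shares of cluster 29, germinal centre B and macrophages at -0.07, 2.33 and -0.32. Without HFD mouse 1, Areg was at 0.02, Gzma in NK and ILC1 at -0.01, and the shares of gamma-delta T and plasmacytoid dendritic cells at 0.31 and 0.15. Without HFD mouse 2, the shares of ILC3, cluster 28, cluster 29, germinal centre B and macrophages were at -0.16, -1.37, -0.29, 0.39 and -1.03. Without HFD mouse 3, Csf2 was at 0, the heat shock list in B cells had an adjusted p of 0.906, and the shares of cluster 11 and gamma-delta T were at -0.22 and 0.01. In cluster 16 only, Il22 was at 0 and Csf2 at 0.19, in cluster 6 only Vegfa at -0.21, and in cluster 17 only Hells, Ccnb2 and Mcm2 at -0.09, -0.23 and -0.19. With TMM factors, the shares of gamma-delta T, germinal centre B, monocytes and plasmacytoid dendritic cells were at 0.31, 0.52, 0.05 and 0.4. With the replicate block, those of germinal centre B and macrophages were at 0.84 and -0.03. Outside the B-like classes, those of ILC2, cDC1, gamma-delta T, monocytes and plasmacytoid dendritic cells were at 0.01, 0.21, 0.34, 0.12 and 0.37, and outside plasma cells as well at 0.21, 0.41, 0.54, 0.32 and 0.56.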

Other observations

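Tests chosen only after the result was seen were those of the captures, of handling, of neighbouring genes, of shares outside the B-like and plasma cells and of the filtered cells. On the cell surface, the tag against integrin β7, which guides cells to the gut, fell in 5 classes. It fell by 0.74 ± 0.10 on the log2 scale in CD8 T cells (n = 3 mice each, edgeR adjusted p = 0.0163), by 1.09 ± 0.18 in cDC2 (0.024), and by 0.73 ± 0.05 in plasma cells (0.000734). In ILC2 the tag named anti-human/mouse integrin β7 fell by 0.44 (0.0403) and in monocytes by 0.41 (0.0387), while RNA of Itgb7 was higher in cDC2 (log2 0.56, adjusted p = 0.00292). The CD31 tag, an adhesion molecule, fell in CD4 T cells, ILC2, cDC2, plasma cells and plasmacytoid dendritic cells, by 1.08 ± 0.12 in ILC2 (adjusted p = 0.00614). In macrophages the CD31 tag did not pass (log2 -1.16, adjusted p = 0.0637), while its gene Pecam1 fell from 200 to 67.3 CPM. The tag CD205 (DEC-205) fell by 0.59 in cDC2 (adjusted p = 0.024), where its gene Ly75 fell as well. The CD103 tag, the integrin of cells within the epithelium, fell by 0.68 in CD8 T cells (adjusted p = 0.0163) and by 0.98 in cDC2 (0.0425). Most tags called were lower in HFD mice, and whether these falls are particular to the tags named was not tested.

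Immediate early and dissociation genes were higher in HFD mice in 10 of 17 classes and lower in 1, by camera with its preset correlation. With an estimated correlation none of these calls held (smallest adjusted p of any list 0.58). A difference between the captures was argued against, since both diets were spread alike over the captures (ILC3 48.9% and 51.6% of UMIs in capture 1). What a difference between the captures gives through this reached at most 5% of the list mean in these 10 classes, in gamma-delta T cells. Chow mouse 3 alone was argued against too, since without it 9 of 10 classes kept the call at the preset correlation. Handling of the tissue that differed between the diets could give the same 10 classes, and the order of handling is not given in the labels, so it cannot be told apart from an effect of the diet.

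The 47 genes called in at least 5 classes formed 11 pairs within 5 Mb of each other, against a median of 5 and a 95th percentile of 10 in random sets (a share of 0.0333 of 10000 sets had as many). Genes were taken as related if their symbols began with the same letters, which left out Lilr4b with Lilrb4a and Myo1e with Myo5a. Without these there were 9 pairs, not above the 95th percentile of 10 (share 0.101). Among the 9 were Slc15a2 with Arhgap31 on chromosome 16, and pairs of Antxr2, Rasgef1b and Lin54 on chromosome 5. Linked sequence that differs between the mice of the diets was therefore left open. Whether such a difference lies behind the rise of Gm47283 on chromosome Y was not tested. For the time of day at collection, clock output genes minus genes of the opposite phase had a median difference of 0.11 (-0.185 to 0.613 over classes). This lay within the limit set in advance as speaking against it. Single clock genes were called in both directions, however. In cDC2, Ciart rose from 1.51 to 3.64 CPM (edgeR adjusted p = 0.0236) and Per2 fell from 14.1 to 7.33 CPM (0.00316). In macrophages, Nr1d2 rose by 0.57 (0.0443) and Clock by 0.44 (0.0463). Means of sets whose members move both ways can hide a shift, so the time of day was left open. An effect of the diet stays open and was not tested apart.

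The smaller shares of CD4 T and CD8 T cells in HFD mice may come from the diet or from how cells were recovered, and these were not told apart. Dilution by B cells was argued against, since outside the B-like and plasma cell classes the log2 ratio nearer to 0 was still -1.55. The filter left out 45, 60 and 60 cells of chow mice 1, 2 and 3, and 69, 67 and 49 of HFD mice. All 185 filtered cells of HFD mice were then counted as the T class, and none of chow mice. The log2 ratios were still -1.64 ± 0.67 (SE) for CD4 T cells and -2.16 ± 0.71 for CD8 T cells. These values argue against the filter as the source of the whole fall. A part was left open, since the rule of this test also asked for a distance in SE that CD4 T cells did not reach.

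Other splits of the 6 mice into 3 and 3 were counted, and 10 splits are too few for a share under 0.05. Only the real split (1 of 10) gave as many genes in B cells (33, highest other 3), CD4 T (33, 2), CD8 T (61, 0), ILC2 (193, 1), ILC3 (297, 2), NK and ILC1 (110, 2), cDC1 (601, 0), cDC2 (2098, 0), cluster 1 (6, 2), cluster 11 (4, 2), gamma-delta T (48, 0), macrophages (489, 0), monocytes (262, 0), plasma cells (27, 1) and plasmacytoid dendritic cells (63, 18). The same held for gene lists (96, 61) and for genes called in at least 5 classes (47, 0). In cluster 10, 4 splits gave as many (1, highest other 3), and for shares of classes 2 did (5, highest other 8). In regulatory T cells all 10 gave as many as the real 0, and the split of chow mice 1 and 2 with HFD mouse 2, the mice with the smallest shares of B cells, gave 240, which points to a structure of the samples. The split with 8 shares called was the same.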
